A study of Mus musculus with 4 samples.

How the data were processed

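The series holds 4 single-colour Affymetrix arrays with 45101 probe sets each, 1 for each of GC and naive B cells from pLN and PP. Per the labels' protocols, RNA was extracted with TRIzol from sorted cells and biotinylated cRNA was hybridised, and GCOS produced the signals, per the submitters' processing notes, which give no version. The algorithm and target of that scaling are not given in the sources used here. The deposited values are intensities on a linear scale, in which every array has a median of 1. Multiplied by 56.4 (GC pLN), 50.0 (naive pLN), 68.0 (GC PP) and 63.3 (naive PP), 100% of the values below 1 fell on steps of 0.1 within the rounding of the file, so the deposited intensity is read as a signal divided by the array's median.

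The 2% trimmed means of the deposited arrays ranged from 7.35 to 10.0, so each array was scaled to a trimmed mean of 500, the rule fixed for arrays that differ by over 10%. The 4 factors above were computed by this same rule and rounded, so their match with it is no separate support. Scaling assumes that the bulk of the signals is equal between cell types. A list of genes of other tissues (63 probe sets) served as background: its median signal, 15.1, was added before taking log2, and its 90th percentile on each array was the detection level. That level was 175 on GC pLN, 85.2 on naive pLN, 271 on GC PP and 231 on naive PP. The unequal levels make fewer genes count as detected on the PP arrays. Log2 folds are on the log2(signal + offset) scale and understate the change of dim genes. Folds written as "-fold" are ratios of signals, over the geometric means of the 2 tissues where they compare cell types.

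Of the 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211, controls included, were not listed. The Entrez identifiers of 34754 probe sets matched the RefSeq gene table, which changed 0 symbols. Each of the 18194 genes was represented by its probe set with the highest mean log2 signal, and 9012 genes had more than 1. Where the text gives the range of a gene's probe sets, it is that of the mean GC-naive log2 fold over probe sets above the level on both arrays of a cell type. Of 368 genes on 26 lists fixed in advance, 327 were measured and the others were not analysed here. 0 columns of the table were left unused.

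GC and naive cells were compared with limma (version 3.58.1, R 4.3.3), with tissue as a block, an intensity trend and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Genes above the detection level on both arrays of at least 1 cell type were tested. The estimate of spread rests on 1 residual degree of freedom and a prior of 13.8. In 20 simulations of this comparison over 8650 genes, a median of 11 (range 0 to 18) of 100 genes changed by a log2 fold of 1 and 82 (38 to 90) of 100 changed by 2 were recovered. Between 1.69% and 24.2% of calls were false, median 15.6%, so the adjustment was looser than its threshold in this setting. Only these 200 genes were changed, far fewer than were called in the data, and the simulated prior had a median of 44.7. The share of false calls need not hold for the data. All comparisons of 1 array with 1 array are described without a test, by counts of genes at 2-fold or more that were above the level on the brighter array. P-values measure only the disagreement between the 2 tissues, not the variation between mice, which pooling removed.

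A list's median was placed among 10000 random lists of the same size matched in 20 bins of mean expression, which describes these arrays and is not a test. Named genes followed a rule fixed in advance. It took the 12 highest and 12 lowest GC-naive folds among called genes, the 10 highest and lowest PP-pLN folds in both cell types and the 5 in each. It also took the 6 largest differences of the fold either way, up to 4 members of each list by fold, and Fas and Ptprc. Bcl6 was named outside this rule, after its values were seen. Alternatives covered the scaling, offset, filter, probe set choice, block, trend, fold threshold and each array left out. These choices, the design and the lists were made before the data were examined, except that 4 alternatives were added afterwards. Coordinates were not used.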

Results

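Gene expression was measured in 4 populations of mouse B cells, each on a single array. Germinal centre (GC) B cells, which proliferate and mutate their antibody genes during an immune response, were sorted as B220+PNA+Fas+ cells, and naive B cells as B220+PNA-Fas- cells. Both came from peripheral lymph nodes (pLN) of C57BL/6J mice immunised with the hapten-protein conjugate TNP-KLH in incomplete Freund's adjuvant, and from Peyer's patches (PP), the lymphoid follicles of the small intestine, of untreated mice. Each RNA sample was pooled from 3 to 5 mice, so there was 1 array per group and the number of arrays limits the precision of every value. Between 7411 genes (naive PP) and 9421 genes (naive pLN) of 18194 lay above the detection level of their array.

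The 2 cell types differed in a sign of RNA quality. The ratio of the 3' to the 5' control probe set of Gapdh was 1.48 on the GC pLN array and 1.67 on the GC PP array, against 18.7 on the naive pLN array and 96.4 on the naive PP array. The Actb controls gave 1.52, 1.82, 12.2 and 67.2 in the same order. The naive arrays therefore carried a strong 3' bias that moved with cell type, and it bears on every GC-naive value below. The 9 bacterial and phage spike-in probe sets, which had median signals of 4263 and 4037 on the GC arrays, stood at 9772 and 19789 on the naive pLN and naive PP arrays.

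**Figure D1:**
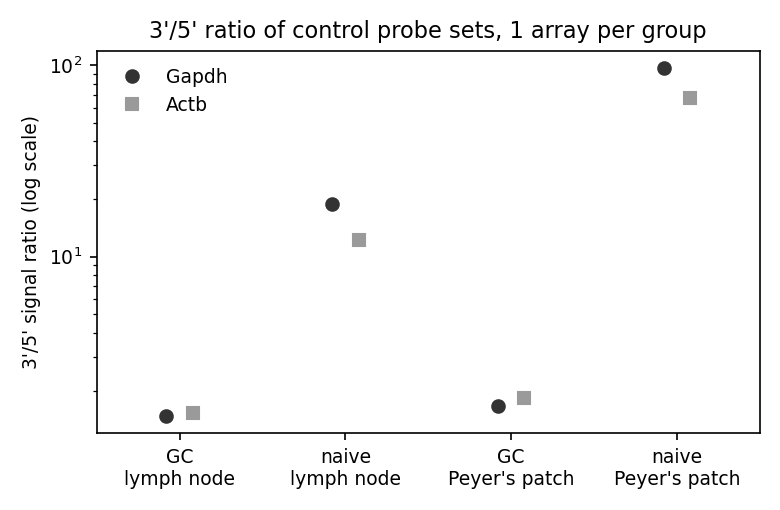
Ratio of the 3' to the 5' control probe set signal (log axis, no unit) for Gapdh and Actb on each of the 4 arrays. Both naive arrays lie above both GC arrays, and naive PP lies highest, at 96.4 for Gapdh and 67.2 for Actb.

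The first comparison asked which genes distinguish GC from naive B cells in both tissues. GC cells had much higher transcripts of cell division genes and of known GC regulators, and mostly lower transcripts of naive and follicular B cell genes and of interferon-induced genes. Fas, the sort marker, was higher in GC cells by 3.30 ± 0.38 (log2 fold ± SE over the 2 tissues, limma adjusted p = 1.7e-05), with signals of 4266 against 515 in pLN and 4980 against 403 in PP. Ptprc, which encodes the B220 antigen on which both populations were selected, differed by -0.20 ± 0.38 and was not called, and its probe sets ranged from -0.20 to 2.53. Of 8650 genes tested with limma, 2156 were higher and 2228 lower in GC cells at an adjusted p under 0.05. The error in this test is the disagreement between the tissues, with 1 residual degree of freedom moderated over all genes. In simulations that changed only 200 genes, a median of 15.6% of its calls were false, a share that need not hold for these calls. The split also depended on the probe sets: with the mean of all probe sets of a gene, 2364 were higher and 1507 lower. With GC PP left out 917 were higher and 720 lower, and with GC pLN left out 1029 and 793.

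The largest increases in GC cells included Rgs13, a regulator of G protein signalling, at least 25.8-fold, Pclaf, a PCNA-binding factor, at least 32.7-fold, and Shcbp1, at least 24.0-fold. Such bounds are given where a gene lay under the detection level on both arrays of the dimmer cell type, and they set the bright signals against the level itself. Gcsam, a GC-associated signalling protein, was at least 22.2-fold higher, Nusap1, a spindle protein, at least 19.8-fold, and the transcription factor gene Mybl1 at least 13.2-fold. Cdkn3 (at least 14.5-fold), Atad5 (23.7-fold), Ranbp9 (20.9-fold), Ube2g1 (14.9-fold) and Spag5 (20.6-fold), by the same kind of bound, and Rassf6 (6.06 ± 0.44, at least 5.00) completed the 12 highest. A bound after a log2 fold, as for Rassf6, marks a gene below the level on 1 array of the dimmer cell type and sets that signal at the level; the fold and SE before it rest on a signal not above background. The bounds leave the order among these genes unresolved. They also take no account of the 3' bias. The Gapdh 5' control read 7068 in GC against 949 in naive cells of pLN, and 6473 against 328 in PP. Its 3' probe set was lower in GC cells of both tissues. Rgs13, Shcbp1, Cdkn3 and Rassf6 had only 1 probe set each, so the bias cannot be weighed for them. The 12 lowest were Dglucy, Rnf144a, Slfn8, Terb1, Ptpdc1, Serpinb1a, Rbpms, Kctd14, Fbxw10, Fuca1, Crip3 and Rgl1. Slfn8, a member of the Schlafen family, was 34.2-fold lower in GC cells, the protease inhibitor gene Serpinb1a 25.8-fold and Fuca1, a lysosomal fucosidase, 20.6-fold, although a second probe set of Fuca1 differed by only -0.23. Dglucy was at least 9.64-fold lower and Crip3 at least 10.2-fold lower.

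Genes of the cell cycle rose together. All 19 measured mitosis genes were called higher, with a median log2 fold of 4.36 (above all 10000 random lists matched on expression). Top2a, the topoisomerase that untangles chromosomes, read 5144 and 5467 in GC cells of pLN and PP and 241 and 43.6 in naive cells. Birc5, a chromosomal passenger protein, was higher by 5.42 ± 0.47 (at least 4.59), and the motor protein gene Kif11 at least 13.3-fold. Of 21 DNA replication genes 17 were higher and 4 were not called (median 2.18). Among these, Cdc6, which loads the replicative helicase, was at least 14.5-fold higher, Pola1 at least 11.8-fold, and Rrm2, a subunit of ribonucleotide reductase, rose by 4.60 ± 0.43 (at least 4.40). Counts adjusted over the list alone were the same for both lists. All 9 mitosis genes with several probe sets above the level had every probe set higher in GC cells, as had 11 of 15 replication genes.

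Other lists tied to the GC reaction showed the same direction. Of 13 genes of the GC programme, 10 were higher, none was lower and 3 were not called (median 3.94, counts adjusted over the list alone identical). S1pr2, a receptor that confines B cells to the follicle centre, rose by 5.84 ± 0.50 (at least 4.36), while Bcl6, the master transcription factor of the GC, differed by 0.79 and was not called (adjusted p = 0.136, limma), although its probe sets ranged from 0.79 to 2.81. Of 8 dark zone genes, 6 were higher, among them Hmmr, at least 14.2-fold, and the proliferation marker Mki67, which was 21.2-fold higher; 1 was lower and 1 not called, also adjusted over the list alone. Several dark zone genes are themselves mitosis genes. Of 16 DNA repair genes, 12 were higher, 1 lower and 3 not called, or 13 higher and 2 lower adjusted over the list alone. The checkpoint kinase gene Chek1 was at least 17.4-fold higher, Exo1 at least 7.13-fold, and Polh, an error-prone polymerase used in hypermutation, was 7.34-fold higher.

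Naive and follicular B cell genes were mostly lower in GC cells. Of 14 naive and follicular genes, 11 were lower, 2 higher and 1 not called, also adjusted over the list alone (median -1.63, 0.04 percentile of random lists). Cd55, a complement regulator, was 16.2-fold lower, and Ccr7, which guides cells to T cell zones, 10.9-fold lower. Klf2, a quiescence factor, fell by 2.51 ± 0.50 (at least 2.32) and Gpr183, which guides cells to the outer follicle, by 2.47 ± 0.42. Only 3 of the 7 members with several probe sets above the level had all of them lower in GC cells, and the 3'/5' ratios of the naive arrays were the high ones given above. The spike-in signals were also lower on the GC arrays, at 4263 against 9772 in pLN and 4037 against 19789 in PP. These gaps are of the same order as the list median. Both the size of the decrease and its direction therefore depend on the scaling, and no scaling to the spike-ins was run. The same limit bears on the other lists called lower. The random lists compare these genes with others of like expression.

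B cell receptor signalling genes were mostly lower, 9 of 15, with 1 higher and 5 not called, and the same counts adjusted over the list alone. Their median of -1.40 lay at the 12.4 percentile of random lists, since bright genes as a class were lower on the GC arrays. It was -0.57 after cyclic loess, -0.79 with quantile normalization and -0.72 with the mean of all probe sets. The median log2 fold went from 0.63 in the dimmest eighth of tested genes to -0.997 in the brightest. Ptpn6, a phosphatase that restrains the receptor, was 4.13-fold lower. Syk, the kinase next to the receptor, and Vav1 were 6.90-fold and 4.58-fold lower by their brightest probe sets, but another probe set was higher in GC cells by 1.83 for Syk and 2.51 for Vav1. Cd22 was 3.90-fold lower, with another probe set at 0.17. Of 10 MHC class II presentation genes 5 were lower, 1 higher and 4 not called, with the same counts adjusted over the list alone and a median of -1.09 at the 47.5 percentile. That median came near 0 after cyclic loess (-0.032), with quantile normalization (-0.016) and with the mean of all probe sets (-0.15). The costimulatory gene Cd86 rose by 1.64 ± 0.37, H2-Oa was 2.58-fold lower, and the probe sets of H2-DMa (-1.44 and 3.23) and H2-DMb2 (-1.48 to 2.37) pointed both ways.

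Of 12 light zone and activation genes, 5 were higher, 2 lower and 5 not called, or 6 higher and 3 lower adjusted over the list alone. Egr2 was 4.65-fold higher and Batf rose by 2.07 ± 0.48 (at least 1.70), while Ccnd2, a cyclin of early G1, was 6.06-fold lower. Slamf1 was 7.16-fold higher, but its probe sets ranged from -0.80 to 2.80. The list median of 0.46 turned negative without the filter on dim genes (-0.06), under a stricter filter (-0.16) and with the probe set brightest on the naive arrays (-0.11).

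**Figure D2:**
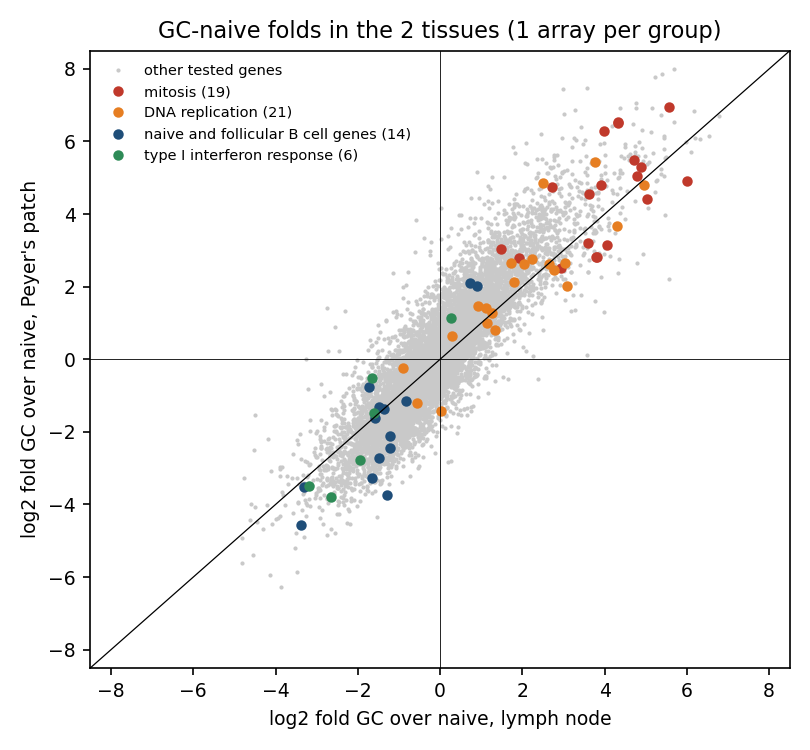
GC-naive log2 folds of the 8650 tested genes in pLN (x axis) and PP (y axis), 1 array per group, with 4 gene lists coloured and the line of equal folds drawn. The 19 mitosis genes lie in the upper right quadrant, and folds correlate across genes with r = 0.89.

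Among 14 chemokine and trafficking receptors, 5 were higher and 5 lower, also adjusted over the list alone. S1pr2 and Cxcr3, an inflammatory chemokine receptor (3.54 ± 0.55, at least 1.76), rose, and Itgb7, an integrin subunit used for homing to the gut, was 13.0-fold lower. Of 13 genes of the TGF-beta, retinoid and IgA switching list, 2 were higher, 3 lower and 8 not called, unchanged when adjusted over the list alone. Tgfbr1 rose by 4.90 ± 0.49 (at least 3.81) and Smad7, an inhibitor of the pathway, by 2.29 ± 0.41 (at least 2.21), while Smad3 was 5.97-fold and Tgfbr2 3.83-fold lower. Among 11 apoptosis regulators, 3 were higher (Pmaip1, at least 5.35-fold, Apaf1 and Bcl2l11), 2 were lower and 6 not called, also adjusted over the list alone. Mcl1 was 2.71-fold lower by its brightest probe set, with probe sets from -1.86 to 2.90.

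Interferon-induced genes were lower in GC cells, 5 of 6 tested, also adjusted over the list alone (median -1.96, 0.09 percentile). Ifit3 fell by 3.34 ± 0.43 (at least 2.39) and Mx1, an antiviral GTPase, by 3.21 ± 0.43 (at least 2.38), and the list median was -1.26 under a stricter filter; none of the 6 had several probe sets above the level with which to weigh the 3' bias. Of 5 immediate early and stress genes, 3 were higher and 2 not called, also adjusted over the list alone: Fos was at least 19.3-fold higher and Dusp1 rose by 2.71 ± 0.54 (at least 2.16). Hspa1b was called at 1.67 ± 0.59, but differed by 0.23 in pLN, and with its naive PP signal at the level it stood at 0.63 and was not called (adjusted p = 0.161, limma). Of 10 plasma cell genes, 5 were higher and 5 not called, also adjusted over the list alone. Jchain, which joins polymeric IgA and IgM, was 8.34-fold higher and Mzb1 rose by 3.75 ± 0.62 (at least 3.10). Of 11 glycolysis genes, 4 were lower, 1 higher and 6 not called; the glucose transporter gene Slc2a1 was 8.15-fold lower and Hk2 2.90-fold higher. The glycolysis median of -0.32 turned positive with quantile normalization (0.29), after cyclic loess (0.40) and with the mean of all probe sets (0.65). Of 14 oxidative phosphorylation genes, 3 were lower (Cox5b among them, 4.09-fold), 2 higher (Cox5a, 3.35-fold, and Ndufa9) and 9 not called. Counts adjusted over the list alone were the same for both. Of 3 immunoglobulin constant genes, Ighm and Ighg3 were called lower and Igha was not called, also adjusted over the list alone, but the 9 probe sets of Ighm above the level ranged from -1.94 to 4.89 and those of Ighg3 from -1.40 to 1.05. Signals of such related genes are uncertain, since probes can cross-hybridise.

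**Figure D3:**
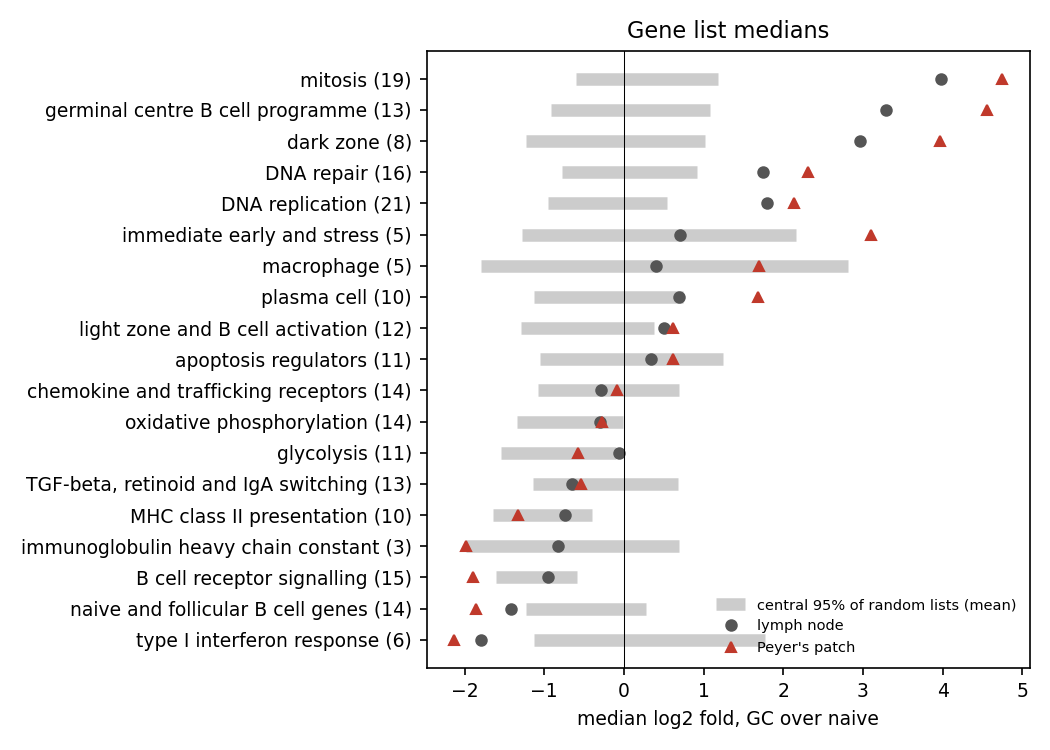
Median GC-naive log2 fold (x axis) of each fixed gene list with at least 3 tested genes, number tested in brackets, in pLN (circles) and PP (triangles). Grey bars hold the central 95% of random lists for the mean of the tissues, and the mitosis list stands at 3.98 in pLN and 4.75 in PP.

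Markers of other cell types were mostly dim. Of 13 T cell markers, 7 were above the level on the naive pLN array, whose level was the lowest, and 1 on each other array. Cd8a read 548 on naive pLN and 127 on GC pLN and was the only one tested and called lower (-1.23 ± 0.48, adjusted p = 0.0436, limma), or by at least 1.03 with GC pLN at the level. Of 12 macrophage markers 5 were tested, and Apoe, a lipid carrier (7.76-fold), and Lyz2 (at least 2.14-fold) were higher in GC cells. Flt3, from the dendritic cell list, was at least 8.22-fold higher in GC cells, and Clu, from the stromal list, was lower by 1.34 ± 0.45, but was not called with its GC pLN signal at the level (-0.74, adjusted p = 0.1, limma). The only tested genes of the gut epithelium and erythroid lists, Lgals4 and Car2, were not called over all genes. Over the list alone Lgals4 was called lower and Car2 higher, but with 1 tested gene in each list this is no adjustment. With its dim naive signal at the level, the log2 fold of Car2 went from 1.22 to 0.67. No granulocyte gene was tested.

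The GC-naive folds were then compared between tissues. In pLN, 1862 genes were at least 2-fold higher and 2497 lower in GC cells of 9756 above the level on either array. In PP, 2732 were higher and 2558 lower of 8793. These counts have no test, since each group is 1 array. Among the 8650 tested genes, 1625 were 2-fold higher in both tissues, against 537 if the lists were independent, and 1719 were lower in both, against 607. The folds correlated across genes with Pearson's r = 0.89 and Spearman's rho = 0.89, and genes are not independent replicates. With no filter on dim genes, Pearson's r was 0.76. Both tissues set a 3'-biased naive array against a GC array, so this agreement does not separate cell type from that bias. The spread of folds was wider in PP (SD 1.88) than in pLN (SD 1.41), as was the gap in 3'/5' ratio.

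The GC-naive fold was larger in PP for Copg2, Ncoa5, Arhgap33, Atp1b1, Fscn1 and Klhl9. Fscn1, an actin-bundling protein, read 3054 against 881 in pLN and 6449 against 96.1 in PP, and Ncoa5 read 1298 against 695 and 1652 against 31.7. Except for Atp1b1, these genes were below the level on the naive PP array. Klhl9 was also below the level on GC pLN, so a larger fold in PP is not measured for it. The fold was smaller in PP for Zkscan6, Plcb2, Igha, Cnr2, Nudt16 and Klf2. Cnr2, a cannabinoid receptor, read 1070 against 3122 in pLN and 328 against 6913 in PP. The probe sets of Nudt16 ranged from -1.97 to 2.02. Those of Igha disagreed in PP. The one used read 14683 in GC against 21321 in naive cells, but the others read 15042 against 8754 and 10107 against 1788. None of these differences was tested.

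The last comparison set PP of untreated mice against pLN of immunised mice, so tissue and immunisation cannot be separated. The GC cells of the 2 tissues were close: 230 genes were at least 2-fold higher in PP and 136 lower, of 8591, and the arrays correlated across tested genes with r = 0.96. The naive cells, with unequal 3' bias, differed more, with 702 genes higher in PP and 1517 lower of 9474 (r = 0.92). In both cell types together 27 genes were higher in PP, against 6.83 if independent, and 41 lower, against 19.6. The naive and GC cells of a tissue may share mice, so none of this was tested. Several counts changed by more than 1.5 times with the filter, the fold, the probe sets or the background list used. With Gh and Prm1 left out of that list, 629 genes were higher and 229 lower in PP in GC cells, and 85 were higher in both. With signals under the level set to the level, 943 genes were lower in PP in naive cells, 84 in GC cells and 21 in both.

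Igha, the constant region of IgA, differed most. It read 14683 in GC and 21321 in naive cells of PP, against 279 and 41.2 in pLN, and its other 2 probe sets were also higher in PP in both cell types. Transcripts of the intestinal lining were likewise higher in PP: the fatty acid binding protein genes Fabp1 (543 in GC and 1389 in naive cells, against 18.9 and 25.4) and Fabp2 (380 and 650, against 8.52 and 22.7), and the goblet cell product Zg16 (556 and 1806, against 17.7 and 90.4). The 3 gut epithelium genes above the level on both PP arrays, a filter that favours genes high in PP, had median log2 folds of 2.52 in naive and 3.98 in GC cells, and all 13 measured had 1.46 and 2.02. With signals under the level set to the level, the 3 had medians of 1.66 and 0.93. Over all 13 the medians were then 1.30 and 0.59, which reflect the unequal levels, so the size over the list is not measured. Reg3b, Cd300lf, Tgm2, Chst11, Rab37 and Slc9a5 completed the 10 highest in both cell types. In naive cells Krt8, an epithelial keratin (1241 against 19.0), and Ckmt1 were also among the 5 highest.

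Interferon-induced genes were lower in naive cells of PP, while in GC cells most lay below the level in PP. All 11 measured genes of that list read lower in PP in each cell type, with median log2 folds of -1.59 in naive and -1.47 in GC cells, but only 3 were above the level on GC PP and 6 on naive PP. The 7 above the level on both pLN arrays, a filter that favours genes high in pLN, had medians of -1.30 and -1.04. Among random lists of genes under the same filter these lay at the 0.625 and 0.01 percentiles, and 4 of the 7 read 2-fold lower in both. With signals under the level set to the level, the 7 had medians of -1.21 in naive and -0.38 in GC cells, 7 and 5 of them were lower in PP, and none was 2-fold lower in GC cells. Over all 11 the median was then -1.21 in naive cells but 0.27 in GC cells, so the size in GC cells is not measured. Mx1 read 473 and 3027 in GC and naive cells of pLN and 74.7 and 1220 in PP. Oas3, Usp18 and Ifit1bl1, also interferon-induced or related to such genes, were among the 10 lowest in both cell types, with Lifr, Slpi, Gpr146, Tbxa2r, Arhgef18, Art4 and Ppfia4. With signals under the level set to the level, Oas3, Gpr146, Art4 and Ppfia4 were not lower in GC cells of PP, nor Art4 in naive cells, so those directions are not measured. Slpi, a secreted protease inhibitor, read 4973 and 688 in GC and naive cells of pLN and 828 and 11.8 in PP. The chemokine and trafficking list had a median of -0.33 in GC cells (0.04 percentile) and -0.34 in naive cells (20.2 percentile), and the naive and follicular list -0.39 in GC cells (below all random lists) and -0.092 in naive cells (26.8 percentile). In GC cells S1pr4 read 1587 in pLN and 330 in PP, and S1pr3 4546 and 1871.

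**Figure D4:**
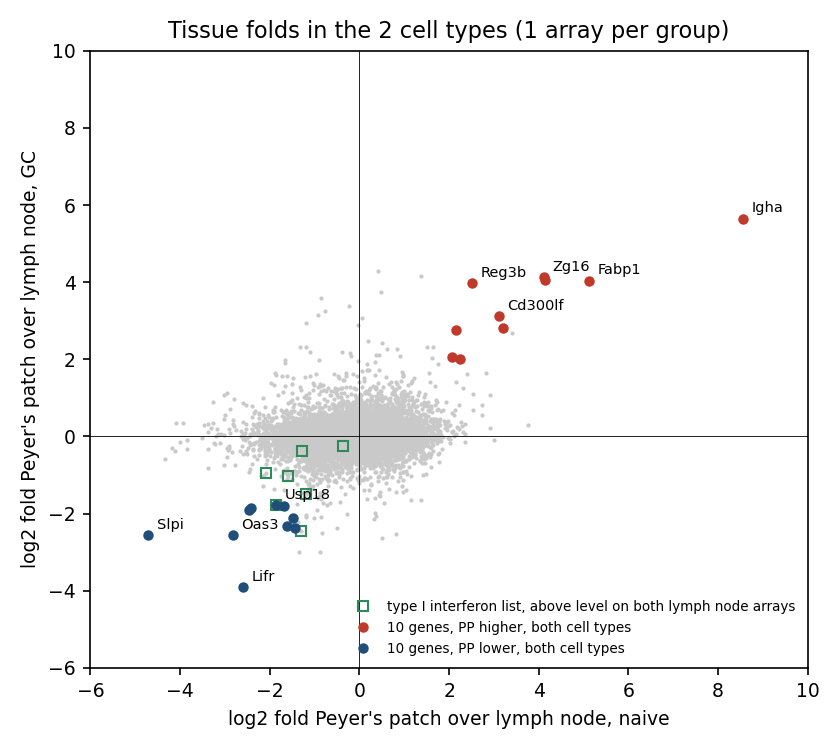
PP-pLN log2 folds in naive (x axis) and GC (y axis) B cells, 1 array per group, with the 10 highest and 10 lowest genes in both cell types and the interferon list marked. Igha lies farthest out, at 8.57 in naive cells, where its pLN signal is below the level, and 5.65 in GC cells.

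Genes were also ranked by their PP-pLN fold within each cell type. In GC cells, Tox2, a nuclear factor, read 5080 in PP and 244 in pLN, and Osbpl3 read 2016 and 86.5. Shtn1 and Fam135a were also among the 5 highest in PP. The lowest in PP besides Lifr were S100a9 and S100a8, granulocyte proteins that read 481 and 209 in GC cells of pLN and lay below the level of 271 in PP, which is above the pLN signal of S100a8, and Lfng and Stac2. Lfng was also lower in naive cells of PP, at 249 against 662. In naive cells Gpr65, Casp2, Cited2 and Copg2 were lowest with Slpi, and all 5 lay below the level on the naive PP array, the array with the highest 3'/5' ratio.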

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

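Of the tests reported here, the probe set and scaling tests of the cell cycle genes were set before their values were seen. Those of the naive and follicular genes, Igha and the gut transcripts were chosen only after the results were seen.

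The 3' bias of the naive arrays was flagged as a signal in control probe sets that no comparison used: on naive PP the 3'/5' ratio was 96.4 for Gapdh and 67.2 for Actb. Over the 24 mitosis and replication genes with several probe sets above the level, each gene's least raised one had a median log2 fold of 2.03. All probe sets were higher for 20 of these genes. This passed the bound set against the bias as the whole cause, but cannot decide the question, because probe positions were not used. The 5' control probe sets themselves were higher in GC cells, by 2.88 in pLN and 4.24 in PP for Gapdh and 2.14 and 2.86 for Actb. Both lists lay above all 10000 random lists, matched on expression, of genes from the same arrays. Scaling that depends on intensity is argued against by a median fold of 2.67 after cyclic loess and 3.08 without it. This leaves a difference between GC and naive cells, and the 3' bias, as hypotheses. For the naive and follicular genes the bias stays open and may account for part of the decrease: over the 7 with several probe sets, the least lowered one had a median of 0.32, and only 3 genes had all probe sets lower. Of all genes called higher with several probe sets, 659 of 807 (81.7%) had every one higher, and of those called lower 480 of 965 (49.7%) had every one lower.

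The Igha signal on both PP arrays was weighed for the naive gate, where IgA is not a naive isotype. Plasma cells or their RNA are argued against as the whole source: the 10 plasma cell genes above the level on a naive array had a median PP-pLN log2 fold of -0.78 in naive cells, 7 were lower in PP, and Jchain was at -1.03. That reading is limited, because several of these genes are also expressed in B cells and probe sets of Ighm on the same arrays ran from -5.64 to 1.59. Cross-hybridisation to the other measured heavy chain genes, Ighm and Ighg3, is argued against by an excess of Igha of 4.99 in GC cells and of at least 5.92 in naive cells, where its pLN signal was set at the level, and other isotypes were not analysed here. IgA-switched B cells within the PNA-Fas- gate, a difference between the tissues themselves, stay open and untested.

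Gut epithelial transcripts on the PP arrays are consistent with epithelial cells or their RNA in those samples, although the B220 gate would remove such cells. The median PP-pLN fold over all 13 list genes was 1.46 in naive and 2.02 in GC cells, with 11 and 12 of them higher in PP; Krt8, Fabp2 and Krt19 read 1241, 650 and 927 on naive PP. Only 5 of the 13 were above the level on naive PP and 4 on GC PP, where Krt8 and Krt19 (128 and 117) were below it, so most of these directions are among undetected signals. With signals under the level set to the level, the medians were 1.30 and 0.59, which reflect the unequal levels. The GC value is then under the 1 that the epithelial explanation required in both cell types, so the list median does not decide for it. The list median rose by more than that of the 37 background genes, by 1.07 in naive and 1.87 in GC cells. Of 10000 random draws of background genes, 0% had a median as high, a condition added after that excess was seen. The brighter background signals, which set the detection level, also rose. That level was 231 on naive PP against 85.2 on naive pLN, and 271 on GC PP against 175 on GC pLN. Most list genes lay under it, so a higher background on the PP arrays stays open for the list as a whole. The excess in naive cells only narrowly passed the bound of 1. Expression in the B cells themselves, and the tissue, were not tested.

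In all, 3 genes named by the rule had GC-naive folds of opposite sign in the tissues, each at least 2-fold, and the differences were not tested. The fold in PP minus that in pLN was -5.51 for S100a9, 3.75 for Gpr65 and 4.14 for Atp1b1. In PP, S100a9 and Gpr65 were below the detection level on both arrays, so their direction there is not measured, and the probe sets of Atp1b1 disagreed (-2.04 to 0.18). Atp1b1 was also below the level on GC pLN. With that signal at the level its folds were -1.94 in pLN and 1.40 in PP, so its difference is a smaller one. Of 3361 genes at least 2-fold different in both tissues, with the brighter side above the level, 17 had opposite directions.

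Among the 9160 probe sets without a listed gene, controls left out, 2680 were above the level on an array. Of these, 667 were 2-fold higher and 265 2-fold lower in GC cells in both tissues.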

How the results depend on the processing

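The alternatives with the probe set brightest on the naive arrays, with the background list without Gh and Prm1, with signals under the level set to the level and with all measured list members were chosen after seeing the data. No paired analysis was possible because every group has 1 array, beyond tissue as a block, which the main fit of GC against naive cells includes. Of 106 named genes called between GC and naive cells, 83 kept call and direction in every alternative that tested them. The arrays left out and the fit with no block were not counted. A gene filtered out of an alternative did not count against it, and the alternative of at least 2-fold in each tissue was not checked by gene. With the fit with no tissue block, 1879 genes were higher and 2094 lower. The median fold of tested genes moved from -0.11 to -0.22 under quantile normalization, where 1967 were higher and 2796 lower, and to 0.21 with the mean of all probe sets, where the split was 2364 higher and 1507 lower against 2156 and 2228. Signal over background limits the comparisons of dim genes, and 1 array per group limits all. Unless given otherwise below, the cause was not tested.

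With no filter, which tests more genes, pLN had 3785 genes lower and PP 5420, PP-pLN counts were 2776 higher in naive cells, 885 higher and 255 lower in GC cells, and 243 higher and 65 lower in both. The correlation of folds was 0.76 and the light zone median -0.057. With the stricter filter, which tests fewer genes, 1162 were higher in GC cells, pLN had 934 higher and 1434 lower, and PP 1477 higher. PP-pLN counts were 533 lower in naive cells, 53 higher and 41 lower in GC cells, and 2 higher and 6 lower in both, and the light zone median was -0.16. At 3-fold, a larger threshold, pLN had 1060 higher and 1135 lower and PP 1602 lower; PP-pLN counts were 165 higher and 510 lower in naive cells, 103 and 44 in GC cells, and 13 and 8 in both.

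With the mean of all probe sets, pLN had 1490 genes lower and PP 1461; PP-pLN counts were 331 higher and 999 lower in naive cells, 90 lower in GC cells, and 17 higher and 27 lower in both. The GC-naive fold reversed for Nudt16 (0.024), Vav1 (0.16), H2-DMa (0.90), Pfkp (0.54), Ighm (1.00) and Ighg3 (0.016), as did the PP-pLN fold in naive cells of S1pr3 (0.017) and Ighm (-2.09). Without _x_at and _s_at probe sets, H2-DMa was at 3.23. With the probe set brightest on the naive arrays, Slamf1 was at -0.80 and the light zone median at -0.11. With the background list without Gh and Prm1, PP-pLN counts in GC cells were 629 higher and 229 lower, and 85 were higher in both. After cyclic loess 24 genes were lower in PP in both. With signals under the level set to the level, the median GC-naive fold was 3.59 for mitosis, 2.69 for the GC programme and -1.32 for the interferon list, 943 genes were lower in PP in naive cells, 84 in GC cells and 21 in both, and Hspa1b, Clu, Zg16 and Arhgap33 were not called. The PP-pLN fold then turned positive in GC cells for Oas3 (0.58), Gpr146 (0.50), Art4 (0.12), Ppfia4 (0.46) and S100a8 (0.35) and in naive cells for Art4 (0.92), Cxcr3 (0.55), S1pr2 (0.79) and Tgfbr1 (0.53), because the level itself is higher on the PP arrays.

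Leaving out each array, with no block and the lone array assumed to vary like the other cell type, gave 917 to 3084 genes higher and 720 to 3015 lower. Without GC PP 917 were higher and 720 lower, without GC pLN 1029 and 793, and without naive PP, the array with the strongest 3' bias, 2208 and 2734. The fold of Zg16, -1.68 with all arrays, ran from -3.74 to 0.38, and that of Cd300lf, -1.36, from -2.92 to 0.20. Both turned positive without GC pLN (0.38 and 0.20) and without naive PP (0.38 and 0.19), since cell type and tissue are then not balanced.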

Other observations

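Some plasma cell genes read differently in the 2 GC samples and others did not. Prdm1, the transcription factor that drives plasma cell formation, read 1007 in GC cells of PP and 118 in those of pLN, the latter below the detection level, and Sdc1, a plasma cell surface proteoglycan, read 2024 and 499. Jchain (10618 and 9253), Mzb1 (5133 and 5705) and Sec61b (5624 and 5607) were similar. The plasma cell list had a median PP-pLN log2 fold of 0.30 in GC cells, at the 99.9 percentile of matched random lists, as was the DNA repair list (0.29), and -0.78 in naive cells, at the 1.36 percentile. Sdc1 was chosen after its values were seen, and none of these values was tested.

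Cxcl13, a chemokine made by follicular stromal cells, read 296 in GC cells of PP and 41.9 in GC cells of pLN, and Clu read 396 and 67.2. Ahr, a receptor for dietary and microbial ligands, read 616 and 132 in the same order, and Ccl22, a chemokine from the dendritic cell list, 404 and 68.7. Each pLN value lay below the detection level of its array, 175, so the sizes of these differences are not measured. The level on GC PP was 271, little under the Cxcl13 signal.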
